A study of Rattus norvegicus with 15 samples.

How the data were processed

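Expression was measured on 15 Affymetrix rat gene arrays of cultured oligodendrocyte precursor cells, 3 arrays in each of 5 groups: poly-L-lysine early and late, myelin protein extract early and late, and a group with no named substrate. Groups were taken from the titles, and where the titles and descriptions gave different hours the groups were called early and late. The deposited values are log2 signals, which the authors made by RMA, per the submitters' processing notes. The versions of RMA and limma, and which arrays were normalized together, are not given in the sources used here. A second copy of the value table held the same values in every cell. The authors' deposited lesion table gives a false discovery rate (FDR) for each probe of a comparison of 14 against 5 days post lesion, from limma per the submitters' processing notes. Its 6 columns of single arrays belong to samples outside these groups and were not used.

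Of 28826 probe sets, 15209 carried 1 gene symbol in the annotation of the array, 306 several and 13311 none. Of the 15209, 15178 matched the RefSeq table of the GRCr8 assembly by gene identifier, which was used for names only. The probe set with the highest mean over all arrays was kept for each symbol, which left 14497 genes, 494 of them with more than 1 probe set. No level filter was used. Myrf, Olig2, Hmgcs1 and Mki67 were not analysed here. No pair of arrays held identical values. The correlation between arrays was 0.9799 to 0.9934 within groups and 0.9673 to 0.9945 between groups. The number of arrays and the spread between replicates limit the precision. The median 95% interval reached 0.305 log2 units to either side of a difference and 0.431 in the test of substrate by time.

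A linear model with 1 mean per group was fitted to all 15 arrays with limma 3.58.1 in R 4.3.3 (10 residual degrees of freedom, empirical Bayes variances). It gave 9 comparisons: extract against polylysine at each time, the change of that difference between times, late against early on each substrate, and each of the 4 cultured groups against the group with no named substrate. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison, by the two-sided test of limma. In all, 33 lists of pathway and cell type genes, with 773 of their 862 entries measured, were tested with camera in limma at the preset correlation of 0.01 between genes and again with a correlation estimated for each list, adjusted over the lists of a comparison. Lists with under 5 measured genes were not tested. The results of 1 list, which was not called in any comparison, are not reported here. Gene sets called in 1 comparison were tested by camera in another that shares no arrays with it. The p of these 4 sets was adjusted over the 4 in the fit of all arrays, and in the alternatives a set was called at an unadjusted p under 0.05. Groups, comparisons, lists, named genes and the alternatives below were chosen before the data were examined, except where said.

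The genes named were the 10 that rose and the 10 that fell most among called genes whose groups did not overlap, without symbols that stand for unnamed loci or clones, and in every comparison Pde4a, Pde4b, Pde4c, Pde4d, Mbp, Cnp, Pdgfra and Cspg4. For each list the 2 to 4 members with the smallest adjusted p, or with the highest level where none was called, served as examples. Sox2, Nr4a3, Lpin1, Vldlr, Arc, Klf10, Per2 and other single called members of a list were named after their values were seen.

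The alternatives were the replicate number as a block, a fit of the compared groups alone, leaving out the group with no named substrate, leaving out the 40% of genes with the lowest mean (8698 genes left), all probe sets, the mean of a gene's probe sets, quantile normalization again, centring of each array on its median, a variance trend with robust settings, array weights, an added log2 difference of at least 1, and leaving out each array in turn. A block over only the 4 groups whose numbers paired the arrays, the main component of the spread within groups as a covariate, and combinations of block and estimated correlation were added after seeing the data. The steps were tested on simulated data with the design of these arrays and the spread of each gene, in 5 runs of 14497 genes for each comparison. Genes and arrays were drawn independently there, without the pairing and the correlation between genes seen in the real arrays. Many genes were changed at once in each run, which eases the adjusted threshold. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Random draws were seeded and symbols sorted in the C locale. Probe sets without a symbol, which may include control probe sets, were used only in the count over all probe sets.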

Results

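Oligodendrocyte precursor cells (OPCs) are the dividing glia that give rise to the myelin-forming cells of the brain and spinal cord. RNA from cultured rat OPCs was measured on 15 Affymetrix expression arrays in 5 groups of 3. The labels call the 3 arrays of a group biological replicates and name no separate cultures or animals, so the p-values measure only the spread between these arrays, which may be partly technical. Cells of 4 groups had been plated on poly-L-lysine, a plain adhesive coating, or on a myelin protein extract, with an early and a late group on each. Both labels of the early groups give 4 h. The late groups carry 8 h in their titles and both 4 h and 12 h in their descriptions, and are called late here for that reason. The fifth group has no named substrate: its titles name differentiation for 4 h, while its descriptions place it at the harvest from mixed glial culture. Its condition is left open, and it is called the reference group. A level was obtained for 14497 genes. Array medians lay between 6.536 and 6.678 log2 units. The 95% interval of a difference between groups reached a median of 0.305 log2 units to either side. This precision was limited by the number of arrays and by the spread between replicates.

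The first comparison asked whether OPCs on myelin extract express other genes than OPCs on polylysine. At the early time no gene passed the test. Mbp, which encodes myelin basic protein, averaged 11.16 ± 0.61 log2 units on the extract and 11.24 ± 0.74 on polylysine (SD, n = 3 each), a difference of -0.08 (SE 0.445). Cnp, which encodes an enzyme of early myelin, differed by -0.13 (SE 0.291). Pdgfra, the growth factor receptor that marks OPCs, differed by -0.09 (SE 0.427), and Cspg4, which encodes the NG2 proteoglycan of OPCs, by 0.01 (SE 0.301). The Pde4 genes encode the cAMP-degrading enzymes named in the study's title. Their differences were -0.05 for Pde4a (SE 0.106), 0.08 for Pde4b (SE 0.192), 0.03 for Pde4c (SE 0.154) and 0.15 for Pde4d (SE 0.138). In limma 0 of 14497 genes were called, and 141 (0.973%) had an unadjusted p under 0.05. Without any difference, a test of independent arrays would give a share of about 0.05. With array weights 0 genes were called and 917 (6.33%) had an unadjusted p under 0.05. The 2 groups did not overlap for 931 genes (6.42%), where chance gives 10%. Here and below the 10% takes arrays as unpaired, and is no test for groups whose numbers pair. With the replicate number as a block over the 4 groups whose numbers paired the arrays, 0 genes were called and 328 had an unadjusted p under 0.05. That block lowered the median SE from 0.142 to 0.115, so the SEs given here hold spread that paired arrays share. In simulated data of this design, 84.5% of genes changed 2-fold and 33.7% of genes changed 1.41-fold were called at the early time. The simulated arrays were unpaired and their genes independent, unlike the real ones, so these shares may not hold here. Over the 5 runs 335 genes were changed 1.41-fold, 335 2-fold and 330 4-fold, which eases the Benjamini-Hochberg threshold. If only a few genes differed, a smaller share of them would be expected to be called.

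At the late time the substrates again differed in no called gene. Mbp averaged 11.05 ± 0.72 log2 units on the extract and 11.25 ± 0.52 on polylysine (SD, n = 3 each), a difference of -0.19 (SE 0.445). Cnp differed by -0.17 (SE 0.291), Pdgfra by -0.13 (SE 0.427) and Cspg4 by 0.14 (SE 0.301). Pde4a differed by -0.04 (SE 0.106), Pde4b by -0.01 (SE 0.192), Pde4c by -0.05 (SE 0.154) and Pde4d by 0.08 (SE 0.138). In limma 0 genes were called, 230 (1.59%) had an unadjusted p under 0.05, and the groups did not overlap for 585 genes (4.04%), where chance gives 10%. With array weights 0 genes were called and 590 (4.07%) had an unadjusted p under 0.05. The test of whether the substrate difference itself changed between the times also called 0 genes in limma, with 123 (0.848%) at an unadjusted p under 0.05. Mbp gave -0.11 (SE 0.63) in that test and Pde4d -0.06 (SE 0.195). In the same simulation of independent genes, under the same limits, 2-fold changes were called for 86.6% of genes at the late time. In the test of the change between times the share was 59.1%. Across genes, which are not independent replicates, the early and late substrate differences correlated with a Pearson r of 0.237 and a Spearman correlation of 0.238. Over leave-one-out fits this r ran from -0.122, without late extract array 1, to 0.409, without late extract array 2, and it was 0.127 without early extract array 3, 0.15 without early polylysine array 3, and 0.141 and 0.0731 without late polylysine arrays 2 and 3.

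Among 33 gene lists fixed before the data were examined, 1 stood apart between the substrates at each time. The targets of SRF and YAP, regulators of transcription that respond to adhesion and the actin skeleton, lay lower on the extract at the early time. This list had 24 of 26 members below 0, a median of -0.08 and adjusted p = 0.00688 in camera. Adjusted p = 0.994 with an estimated correlation between genes. Its brightest members were the actins Actg1 at -0.02 (SE 0.0983) and Actb at -0.04 (SE 0.107), and the actin-binding Cnn3 at -0.07 (SE 0.104). The call was lost without early extract array 2 (adjusted p = 0.369), early extract array 3 (adjusted p = 0.402, median 0.01) or early polylysine array 1 (adjusted p = 0.657, median -0.02). It held at medians of -0.22 without early extract array 1 and -0.16 without early polylysine array 2 or 3. Genes of mitochondrial respiration lay lower on the extract at the late time, with 28 of 30 members below 0, a median of -0.09 and adjusted p = 0.00053, against adjusted p = 0.883 with an estimated correlation. Its examples were the ATP synthase subunit Atp5f1b at -0.05 (SE 0.11) and the respiratory chain genes Ndufa4 at -0.10 (SE 0.0944) and Cox6a1 at -0.10 (SE 0.125). This call was lost without late extract array 1 (adjusted p = 0.0683, median -0.05) or 3 (adjusted p = 0.135, median -0.04), and held at -0.16 without late extract array 2 and -0.06 without late polylysine array 2 or 3. None of the members of these lists was called, over all genes or adjusted over the list alone. The extracellular matrix list, at a median of -0.18 and adjusted p = 0.324 at the early time, gave adjusted p = 0.00289 with the block of paired numbers and adjusted p = 0.992 when the correlation was also estimated. Its brightest members were the proteoglycan genes Vcan at 0.21 (SE 0.205), Ncan at -0.17 (SE 0.181) and Bcan at -0.06 (SE 0.231). The median, mean and test of a list did not share a sign for the early heat shock, differentiation inhibitor, mitosis, NF-kB, astrocyte, endothelial and Schwann cell lists. In the late comparison this held for the hypoxia and integrated stress response lists, and in the test of the change between times for the cAMP, TGF-beta and extracellular matrix lists. None of these lists was called there.

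A further test asked whether genes that move on polylysine differ on the extract, using gene sets drawn from arrays that the test did not use. These arrays are not independent of those tested. For equal replicate numbers, the deviations of late polylysine arrays from their group mean correlated at a mean of 0.57 with early polylysine and 0.393 with early extract arrays. Selection alone could therefore push risen genes below 0 and fallen genes above 0. The 895 genes that rose from the reference group to the late polylysine group, among them Asns, Shmt2 and Scd, lay lower on the extract than on polylysine at the early time, with a median of -0.10 log2 units, 92.7% of genes below 0 and adjusted p = 2.8e-16 in camera on the limma fit. It was adjusted p = 0.443 with an estimated correlation. Within the replicate numbers 1, 2 and 3 the median was 0.02, -0.04 and -0.29. The 351 genes that had fallen, among them Egr1 and Fos, had a median of 0.06 with 28.8% below 0, at adjusted p = 2.22e-05 and adjusted p = 0.443 with an estimated correlation. Their call was lost without reference array 3 (median 0.02) and late polylysine arrays 2 (0.0013) and 3 (0.02). The 788 genes that rose from the reference group to the early polylysine group had a median of -0.04 at the late time, with 67.6% below 0, adjusted p = 0.00107 and adjusted p = 0.671 with an estimated correlation. That median was 0.02 without late extract array 1, 0.01 without late extract array 3 and 0.02 without late polylysine array 3, and the call was also lost without reference array 2 (-0.02) and early polylysine array 3 (-0.01). The 227 genes that had fallen had a median of -0.01 at adjusted p = 0.826, which was 0.05 without late extract array 2, 0.03 without late polylysine array 1 and -0.04 without late extract array 1.

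The early and late groups on one substrate were then compared. On polylysine the cystine transporter gene Slc7a11 fell 4.3-fold between the early and the late group (log2 difference -2.10, SE 0.308, adjusted p = 0.00806). The neutral amino acid transporter gene Slc1a4 fell 3.77-fold (-1.91, SE 0.211, adjusted p = 0.00122) and Cars1, which encodes cytosolic cysteinyl-tRNA synthetase, 2.86-fold (-1.52, SE 0.215, adjusted p = 0.00669). The receptor kinase gene Met fell 4.59-fold, from 8.58 ± 0.30 to 6.38 ± 0.20 log2 units (SD, n = 3 each). Other genes that fell most were Sv2c (-2.17), a synaptic vesicle glycoprotein gene, Emp1 (-2.08), Mchr1 (-2.06), the neuropeptide precursor gene Pnoc (-1.75), the AP-1 family gene Jdp2 (-1.63) and the metalloprotease gene Adamts9 (-1.57). The genes that rose most were Map2k6, a kinase gene of the p38 pathway, 2.28-fold (1.19, SE 0.207, adjusted p = 0.0163), the thioesterase gene Acot1 (1.00), Tagln3 (0.99), the Notch ligand gene Dll3 (0.86), the glypican gene Gpc2 (0.75), the sodium channel subunit gene Scn2b (0.73), Pgpep1 (0.73), the phosphofructokinase gene Pfkm (0.71), Lzts1 (0.70) and Stmn2 (0.66), whose product regulates microtubules. Mbp differed by 0.01 (SE 0.445), Cnp by -0.08 (SE 0.291), Pdgfra by -0.37 (SE 0.427) and Pde4d by -0.20 (SE 0.138), and none of them was called. In limma 95 genes were called, 20 higher and 75 lower in the late group, and 1 and 27 of these reached 2-fold. A fit of these 2 groups alone called 0 higher and 13 lower. The groups did not overlap for 2242 genes (15.5%), where chance gives 10%. The block of paired numbers gave 514 called genes, 193 higher and 321 lower, including all 95. Leaving out 1 array gave 18 to 67 calls, with 29, 18 and 38 without early polylysine arrays 1, 2 and 3 and 24 without late polylysine array 2. In these fits 10, 10 and 9 of the 10 risen genes named lost their call without early polylysine arrays 1, 2 and 3, and 5, 10 and 6 without late polylysine arrays 1, 2 and 3. Of the 10 fallen genes 3, 4 and 1 lost it without early arrays 1, 2 and 3, and 1, 3 and 0 without late arrays 1, 2 and 3. The adjusted p of Map2k6 ran from 0.0247 to 0.0934 and that of Slc7a11 from 0.0161 to 0.0563.

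On the myelin extract Slc7a11 fell 5.16-fold from the early to the late group (-2.37, SE 0.308, adjusted p = 0.00338), Slc1a4 3.37-fold (-1.75, SE 0.211, adjusted p = 0.002) and Jdp2 3.13-fold (adjusted p = 0.00013). Met (-2.11), Sv2c (-2.05), Emp1 (-1.94), Pnoc (-1.53), Cars1 (-1.47), Adamts9 (-1.47) and the kinase gene Camk1d (-1.46) followed, and a second probe set of Camk1d gave -0.75. Map2k6 rose 2.15-fold (1.10, SE 0.207, adjusted p = 0.0214) and Pfkm 2.07-fold (1.05, SE 0.143, adjusted p = 0.00396). Dll3 (1.05), Gpc2 (1.02), Tagln3 (0.99), Ddah2 (0.94), the FGF receptor-like gene Fgfrl1 (0.90), Pgpep1 (0.90), Serinc2 (0.88) and the semaphorin gene Sema6c (0.86) also rose. Mbp differed by -0.11 (SE 0.445) and Pde4d by -0.26 (SE 0.138), and neither was called. A fit of these 2 groups alone called 0 genes higher and 20 lower. In limma on all arrays 195 genes were called, 57 higher and 138 lower, of which 4 and 36 reached 2-fold, and the groups did not overlap for 2703 genes (18.6%), where chance gives 10%. Quantile normalization of the arrays again gave 97 higher and 126 lower. Leaving out 1 array gave 44 to 825 calls, with 118, 51 and 59 without early extract arrays 1, 2 and 3, and 825, 84 and 44 without late extract arrays 1, 2 and 3. Of the 10 risen genes 2, 4 and 6 lost their call without early extract arrays 1, 2 and 3, and 0, 5 and 6 without late extract arrays 1, 2 and 3. Of the 10 fallen genes 1, 2 and 0 lost it without early arrays 1, 2 and 3, and 0, 1 and 4 without late arrays 1, 2 and 3. The adjusted p of Map2k6 ran from 0.0185 to 0.104 and that of Slc7a11 from 0.00367 to 0.0238. The 2 time comparisons share no array. Their differences correlated across genes with a Pearson r of 0.812 and a Spearman correlation of 0.72. In both, 17 genes were called higher and 62 lower, against 0.0786 and 0.714 for independent lists, and 0 were called in opposite directions. These lists are not independent, since both comparisons share 1 estimate of each gene's spread. The deviations of early arrays with equal numbers also correlated between the substrates, at a mean of 0.568.

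**Figure D1:**
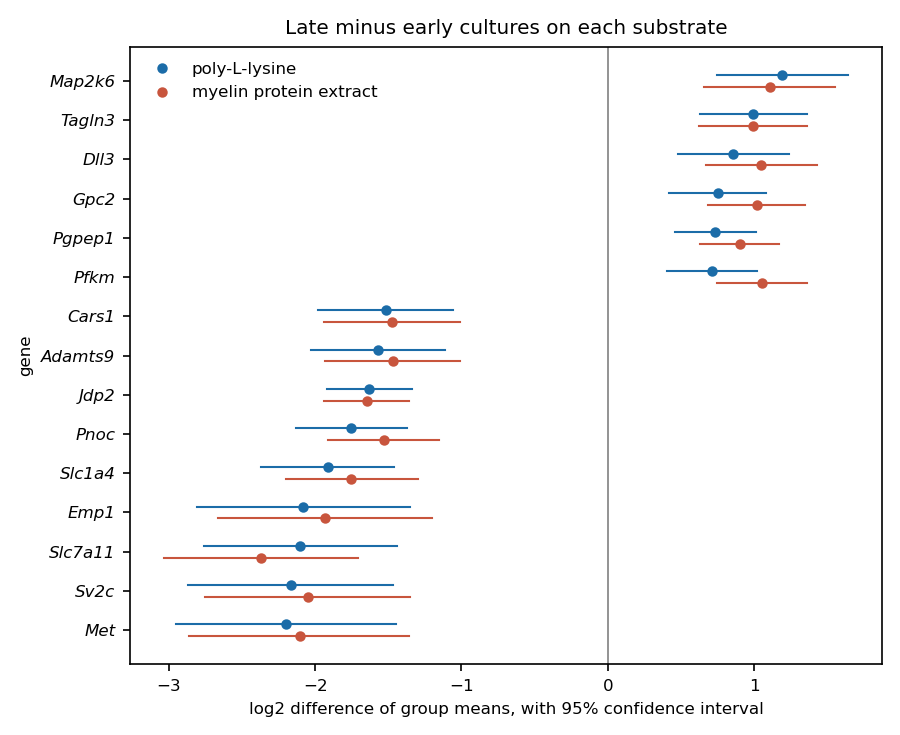
Log2 difference between the late and the early group, with its 95% confidence interval, for the genes named on both substrates by the size rule (blue, polylysine; red, myelin extract; 3 arrays per group). Slc7a11 lies at -2.10 on polylysine and -2.37 on the extract, and Map2k6 at 1.19 and 1.10.

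By list, genes of the integrated stress response, which cells switch on when amino acids or protein folding fail, fell between the early and the late time. On polylysine 8 of 27 members were called lower over all genes and 18 adjusted over the list alone, with a median of -0.77 and adjusted p = 7.55e-20 in camera, and on the extract 8 and 15 with a median of -0.70 and adjusted p = 1.45e-14. Adjusted p = 0.108 and 0.237 with an estimated correlation. Mthfd2, a mitochondrial one-carbon enzyme gene, fell by 1.43 (SE 0.195), the transcription factor gene Cebpg by 0.76 (SE 0.105) and the serine synthesis gene Psat1 by 0.94 (SE 0.145) on polylysine. Feedback targets of the ERK kinases had 2 of 22 members lower on polylysine (8 adjusted over the list alone), Emp1 and Spry2 (-0.66), and 1 (9) on the extract, Emp1, at adjusted p = 7.12e-10 and 3.28e-07. Adjusted p = 0.108 and 0.237 with an estimated correlation. Immediate early genes had medians of -0.32 and -0.21 at adjusted p = 4.81e-06 and 0.000836, with Arc (-0.86) called on polylysine and Klf10 (-0.64) on the extract, and 8 and 6 members called lower adjusted over the list alone. Adjusted p = 0.31 and 0.595 with an estimated correlation. The extract call was lost without late extract array 1 (adjusted p = 0.0798), and its median was -0.34 without late extract array 2. The CREB target list, which shares Fos, Junb, Nr4a1 and Dusp1 with it, had medians of -0.18 and -0.14 at adjusted p = 0.00336 and 0.0157, and the clock gene Per2 was called on both substrates (-0.69 and -0.73), with 3 members lower on each adjusted over the list alone. Adjusted p = 0.351 and 0.595 with an estimated correlation. These calls were lost without early polylysine array 3 (adjusted p = 0.057, median -0.09), early extract array 3 (adjusted p = 0.135, median -0.06) or late extract array 1 (adjusted p = 0.0798), and the extract median was -0.28 without early extract array 1. In the unfolded protein response list the chaperone gene Pdia4 rose (0.56 and 0.67) and Herpud1, which encodes a factor of ER-associated degradation, fell (-1.02 and -0.96), 5 members were higher and 1 lower adjusted over the list alone on each substrate, and the medians were 0.26 and 0.22 at adjusted p = 0.000354 and 0.0157. Adjusted p = 0.108 and 0.237 with an estimated correlation. The extract call was lost without early extract array 3 (adjusted p = 0.0522) or late extract array 1 (adjusted p = 0.0642), and its median was 0.14 without late extract array 2.

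G2/M and mitosis genes had 0 of 32 members called on either substrate in limma, over all genes or adjusted over the list alone, with medians of -0.31 and -0.34 at adjusted p = 0.0174 and 0.017, against adjusted p = 0.992 and 0.948 with an estimated correlation. Top2a, the topoisomerase of dividing cells, gave -0.37 (SE 0.587) on polylysine. A block of paired numbers left 6 mitosis genes lower on polylysine, at adjusted p = 1.78e-12 and 0.244 with an estimated correlation. Without early polylysine array 1 or late polylysine array 3 the median of the list was 0.04 and 0.01, without late polylysine array 2 adjusted p = 0.0863, and on the extract the median was 0.03 without early extract array 1. The extract call was also lost without late extract arrays 1 (adjusted p = 0.0798) and 2 (adjusted p = 0.686, median -0.05). The polylysine median was -0.68 without early array 3 and -0.74 without late array 1, and the extract median -0.74 without early array 3 and -0.70 without late array 3. Ribosomal protein genes had medians of 0.14 and 0.12 at adjusted p = 0.000354 and 0.0126, and genes of mitochondrial respiration 0.12 and 0.11 at adjusted p = 0.000532 and 0.0334, with 0 members called in either list, over all genes or adjusted over the list alone. With an estimated correlation adjusted p = 0.764 for both lists on polylysine and adjusted p = 0.948 on the extract. On the extract both calls were lost without early extract array 3 (adjusted p = 0.13 and 0.265) and late extract array 2 (adjusted p = 0.34 and 0.404, medians 0.05 and 0.04), and that of respiration without early extract array 2 (adjusted p = 0.0541) or late extract array 1 (adjusted p = 0.0798). The ribosomal median on the extract was 0.18 without late extract array 3. Among single members of other lists, Adcy8, an adenylyl cyclase gene, fell by 1.40 (SE 0.227) on polylysine, Vegfa, which encodes an angiogenic growth factor, by 1.27 (SE 0.171) and the chaperone gene Hspa4l by 0.96 (SE 0.143). With the block of paired numbers 5 more lists passed on polylysine. These were the NF-kB and chemokine list, with 5 members higher at adjusted p = 0.000398, the microglia list, with 1 lower at adjusted p = 0.0138, the NRF2 target list at adjusted p = 0.0322, and the interferon and differentiation inhibitor lists, both at adjusted p = 0.0372. Adjusted p = 0.529, 0.849, 0.784, 0.812 and 0.28 with an estimated correlation as well.

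Each cultured group was next compared with the reference group. In the early polylysine group Slc7a11 rose 6.14-fold, from 6.82 ± 0.60 to 9.43 ± 0.35 log2 units (SD, n = 3 each, adjusted p = 0.000401), and Asns, which encodes asparagine synthetase, 6.08-fold (2.60, SE 0.263, adjusted p = 0.000127). Slc1a4 rose 5-fold (2.32, SE 0.211), and the mitochondrial one-carbon enzyme genes Shmt2 by 2.21 (SE 0.226) and Mthfd2 by 2.00 (SE 0.195). The ATF4-induced pseudokinase gene Trib3 rose by 2.09 (SE 0.331), the secreted glycoprotein gene Stc2 by 2.05 (SE 0.233) and the collagen receptor gene Ddr2 by 1.91 (SE 0.364). The amino acid transporter genes Slc7a5 and Slc7a1 rose by 1.99 (SE 0.246) and 1.93 (SE 0.265). The immediate early gene Fos fell 8-fold, from 11.08 ± 0.12 to 8.08 ± 0.33 log2 units (adjusted p = 4.79e-05), Egr1 6.98-fold (-2.80, SE 0.241), Nr4a1 by 1.93, Junb by 1.87 and Egr2 by 1.66. Dusp1, a phosphatase gene of the MAP kinases, fell by 2.19 (SE 0.167), and the prokineticin receptor gene Prokr2 (-1.83), the cytochrome P450 gene Cyp2d2 (-1.60), the matricellular gene Ccn1 (-1.52) and the kininogen gene Kng1 (-1.36) fell as well, and for Kng1 a second probe set gave 0.22. A second probe set of Mthfd2 gave 2.51. Mbp differed by 0.20 (SE 0.445), Pde4b by -0.19 (SE 0.192), Pde4d by -0.10 (SE 0.138) and Pdgfra by -0.71 (SE 0.427, adjusted p = 0.369), and none of them was called. In limma 1015 genes were called, 788 higher and 227 lower, with 90 and 31 at 2-fold or more, and the groups did not overlap for 4305 genes (29.7%), where chance gives 10%. With arrays centred on their medians 1225 were higher and 148 lower. The block of paired numbers gave 2643, 1714 higher and 929 lower, including all 1015, and leaving out 1 array gave 261 to 949, with 407 and 359 without reference arrays 2 and 3 and 407 and 261 without early polylysine arrays 2 and 3. The call of Kng1 was lost without reference array 2 and without early polylysine arrays 2 and 3 (adjusted p up to 0.0651).

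In the early myelin extract group Slc7a11 rose 8.53-fold against the reference group (3.09, SE 0.308, adjusted p = 0.000117) and Asns 6.03-fold (2.59, SE 0.263, adjusted p = 0.000117). Slc1a4 (2.27), Shmt2 (2.10), Trib3 (2.09), Ddr2 (1.93), Slc7a5 (1.92), Mthfd2 (1.92), Stc2 (1.90) and Slc7a1 (1.87) also rose. Fos fell 7.43-fold (-2.89, SE 0.262, adjusted p = 6.11e-05) and Egr1 6.99-fold, followed by Dusp1 (-2.28), Nr4a1 (-2.05), Ccn1 (-1.93), Junb (-1.85), Egr2 (-1.65), Prokr2 (-1.62), the PI3 kinase inhibitor gene Pik3ip1 (-1.38) and Cyp2d2 (-1.38). Mbp differed by 0.12 (SE 0.445), Pde4b by -0.10 (SE 0.192) and Pdgfra by -0.79 (SE 0.427, adjusted p = 0.344), none of them called. In limma 702 genes were called, 487 higher and 215 lower, with 74 and 34 at 2-fold or more, and the groups did not overlap for 4005 genes (27.6%), where chance gives 10%. With arrays centred on their medians 654 were higher and 145 lower. Pairing by number in the block gave 2022, 1136 higher and 886 lower, including all 702. Leaving out 1 array gave 219 to 681, with 376, 219 and 294 without early extract arrays 1, 2 and 3 and 283 and 238 without reference arrays 2 and 3. The calls of Ddr2 (without early extract array 2 and reference arrays 2 and 3), Cyp2d2 (without any early extract array and reference array 2) and Prokr2 (without reference array 3) were lost at adjusted p up to 0.0548, 0.0819 and 0.0626. The different counts on the 2 substrates are not a test of a difference between them, for which 0 genes were called above.

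**Figure D2:**
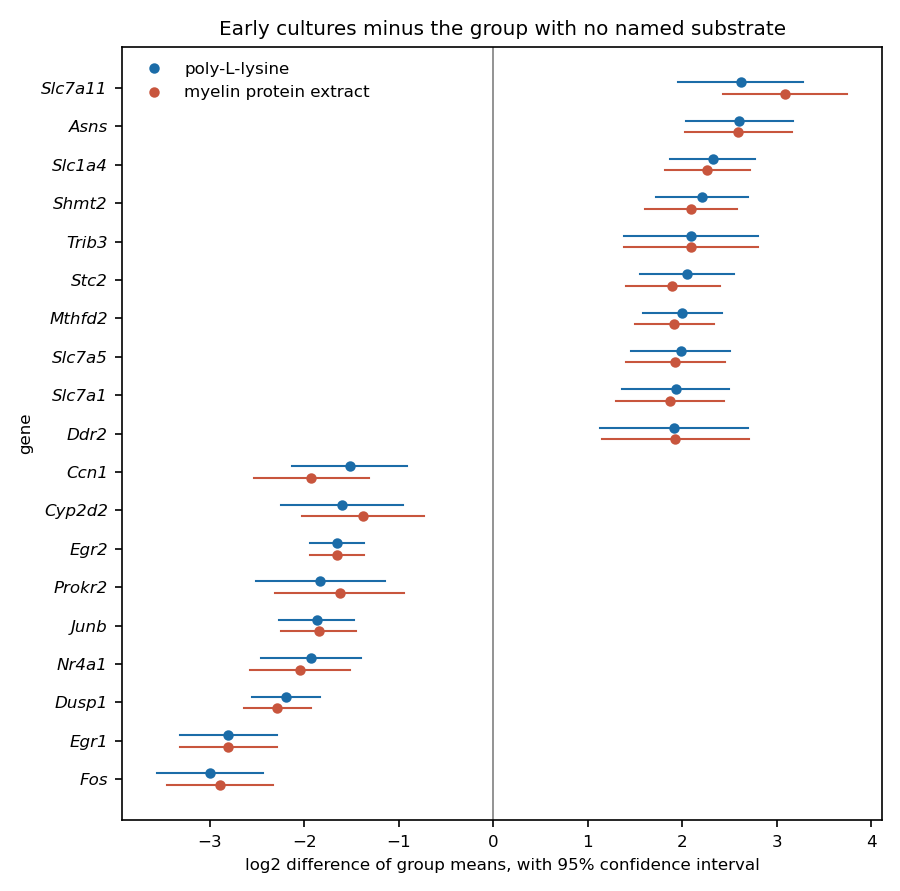
Log2 difference between the early cultures and the reference group, with its 95% confidence interval, for the genes named on both substrates by the size rule (blue, polylysine; red, myelin extract; 3 arrays per group). Slc7a11 lies at 2.62 and 3.09 and Fos at -3.00 and -2.89, and the intervals of the substrates overlap for each of these genes. Both differences subtract the same reference arrays.

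Among lists, 17 of 27 integrated stress response genes rose in the early groups on each substrate over all genes, and 22 on polylysine and 21 on the extract rose and 1 fell on each adjusted over the list alone. Their medians were 1.14 and 1.04 at adjusted p = 8.7e-22 and 8.01e-24 in camera. Adjusted p = 0.0863 and 0.0647 with an estimated correlation. Of 22 genes of cholesterol synthesis and its regulation, 14 rose on polylysine and 13 on the extract, 19 and 17 adjusted over the list alone, with medians of 0.80 on both at adjusted p = 1.51e-11 and 3.78e-13. Adjusted p = 0.262 and 0.239 with an estimated correlation. The extract median was 0.52 without reference array 3. Its examples on polylysine were the late pathway enzyme genes Sc5d (1.02, SE 0.148), Hsd17b7 (1.16, SE 0.214) and Cyp51 (0.87, SE 0.178), and Mvd (1.22, SE 0.242), an enzyme gene of the mevalonate pathway. Immediate early genes had 13 of 29 members lower on each substrate, 17 and 16 lower and 1 and 2 higher adjusted over the list alone, with medians of -0.79 and -0.70 at adjusted p = 3.17e-11 and 3.78e-13, and of -0.46 and -0.43 without reference array 1. Adjusted p = 0.0863 and 0.0647 with an estimated correlation. The CREB target list, with 5 of 23 members lower on each, fell through Fos, Dusp1, Junb and Nr4a1, which both lists hold, and Nr4a3 (-1.03 and -0.91), at adjusted p = 0.00487 and 0.00748 and adjusted p = 0.275 and 0.327 with an estimated correlation. Adjusted over the list alone it had 7 members lower on each and 2 and 3 higher.

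Smaller numbers of genes rose in other lists of the early groups. In the heat shock list 3 of 15 rose on polylysine and 5 on the extract, 5 on each adjusted over the list alone, with Hspa4l at 0.82 and 0.98 and the mitochondrial chaperonin gene Hspe1 at 0.58 and 0.53 (adjusted p = 0.00471 and 0.000415, and adjusted p = 0.0863 and 0.0615 with an estimated correlation). In the list of NRF2 targets, genes of the oxidative stress response, 5 and 2 of 19 rose, 8 and 5 adjusted over the list alone, with Nqo1 at 1.74 and 1.55 (adjusted p = 0.000413 and 0.000415, and adjusted p = 0.298 and 0.327 with an estimated correlation). Of 19 unfolded protein response genes 5 and 1 rose, 8 and 6 adjusted over the list alone, with Herpud1 at 1.20 and 1.04 (adjusted p = 0.00595 and 0.016, and adjusted p = 0.139 and 0.189 with an estimated correlation). Of 17 fatty acid synthesis genes 3 and 2 rose, 7 and 3 adjusted over the list alone, with the lipogenesis regulator gene Mid1ip1 at 1.05 and 0.87 (adjusted p = 0.000905 and 0.00588, and adjusted p = 0.298 and 0.443 with an estimated correlation). Of 30 genes of mitochondrial respiration 5 and 2 rose, 16 and 7 adjusted over the list alone, with Ndufa9 at 0.45 and 0.36 (adjusted p = 4.93e-09 and 6.38e-07, and adjusted p = 0.262 and 0.327 with an estimated correlation). Of 32 ribosomal protein genes 2 and 1 rose, 6 and 1 adjusted over the list alone, with Rpl3 at 0.62 and 0.56 (adjusted p = 1.96e-06 and 2.21e-05, and adjusted p = 0.412 and 0.478 with an estimated correlation). The hypoxia and glycolysis list rose on polylysine with 5 of 28 genes, among them Ddit4 (1.26) and Vegfa (1.16), and with 7 higher and 2 lower adjusted over the list alone (adjusted p = 0.0192, and adjusted p = 0.47 with an estimated correlation). The call was lost without reference array 1 (adjusted p = 0.066) or early polylysine array 3 (adjusted p = 0.0549), and on the extract the list gave adjusted p = 0.11.

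Markers of OPCs lay lower in the early groups than in the reference group. Of 27 genes 22 were below 0 on each substrate, with medians of -0.27 and -0.32 at adjusted p = 0.0174 and 0.00361, against adjusted p = 0.447 and 0.327 with an estimated correlation. The proteoglycan gene Cspg5 fell by 0.70 (SE 0.115) on polylysine and by 0.77 (SE 0.115) on the extract, and Chst3, a sulfotransferase gene, rose by 0.58 (SE 0.164) on polylysine. Over the list alone these gave the same counts, 1 higher and 1 lower on polylysine and 1 lower on the extract. The polylysine call was lost without reference array 1 (adjusted p = 0.0579) or early polylysine array 3 (adjusted p = 0.0694, median -0.15). In the block of paired numbers 8 OPC genes were lower and 1 higher on polylysine and 8 were lower on the extract, and Pdgfra was called lower at adjusted p = 0.00267 on polylysine and 0.00152 on the extract, the lowest of its alternatives, which reached adjusted p = 0.815 and 0.728. Inhibitors of oligodendrocyte differentiation had 4 of 21 members lower and 1 higher on each substrate, 5 and 6 lower and 1 higher adjusted over the list alone (adjusted p = 0.00471 and 0.0025, and adjusted p = 0.212 and 0.189 with an estimated correlation). The member that rose was the stem cell factor gene Sox2 (0.33 and 0.35). The members that fell were the immediate early gene Egr1, the transcription factor genes Klf4 (-1.05 and -1.09) and Zbtb16 (-0.74 and -0.81) and the intermediate filament gene Nes (-0.68 and -0.58). Mitosis genes had medians of -0.42 and -0.41 with 0 of 32 called, at adjusted p = 0.0551 and 0.0465, and adjusted p = 0.892 and 0.822 with an estimated correlation. The extract call was lost without early extract arrays 2 (adjusted p = 0.1) and 3 (adjusted p = 0.945, median -0.07) and reference array 1 (adjusted p = 0.86, median -0.09), and its median was -0.81 without early extract array 1 and -0.69 without reference array 3. With the block of paired numbers 19 and 15 of them were lower, at adjusted p = 6.16e-09 and 3.96e-10, and adjusted p = 0.155 and 0.13 when the correlation was also estimated. G1/S genes, with 0 of 28 called at adjusted p = 0.249 and 0.0636, had 4 and 7 lower with that block, at adjusted p = 0.00695 and 0.000169, and adjusted p = 0.37 and 0.221 when the correlation was also estimated. The medians of microglia markers were -0.32 and -0.36 with 0 of 23 called at adjusted p = 0.355 and 0.25, and with the block 5 and 6 were lower and 1 higher on each at adjusted p = 0.00349 and 0.00102. Adjusted p = 0.635 and 0.528 with the block and an estimated correlation. On the extract the block also called the myelin list, with 2 lower at adjusted p = 0.00431, the committed oligodendrocyte list, with 3 lower at adjusted p = 0.0331, and the fibroblast list, with 2 lower at adjusted p = 0.0462. Adjusted p = 0.574, 0.574 and 0.528 for these lists with the block and an estimated correlation, where no list was called in either comparison.

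**Figure D3:**
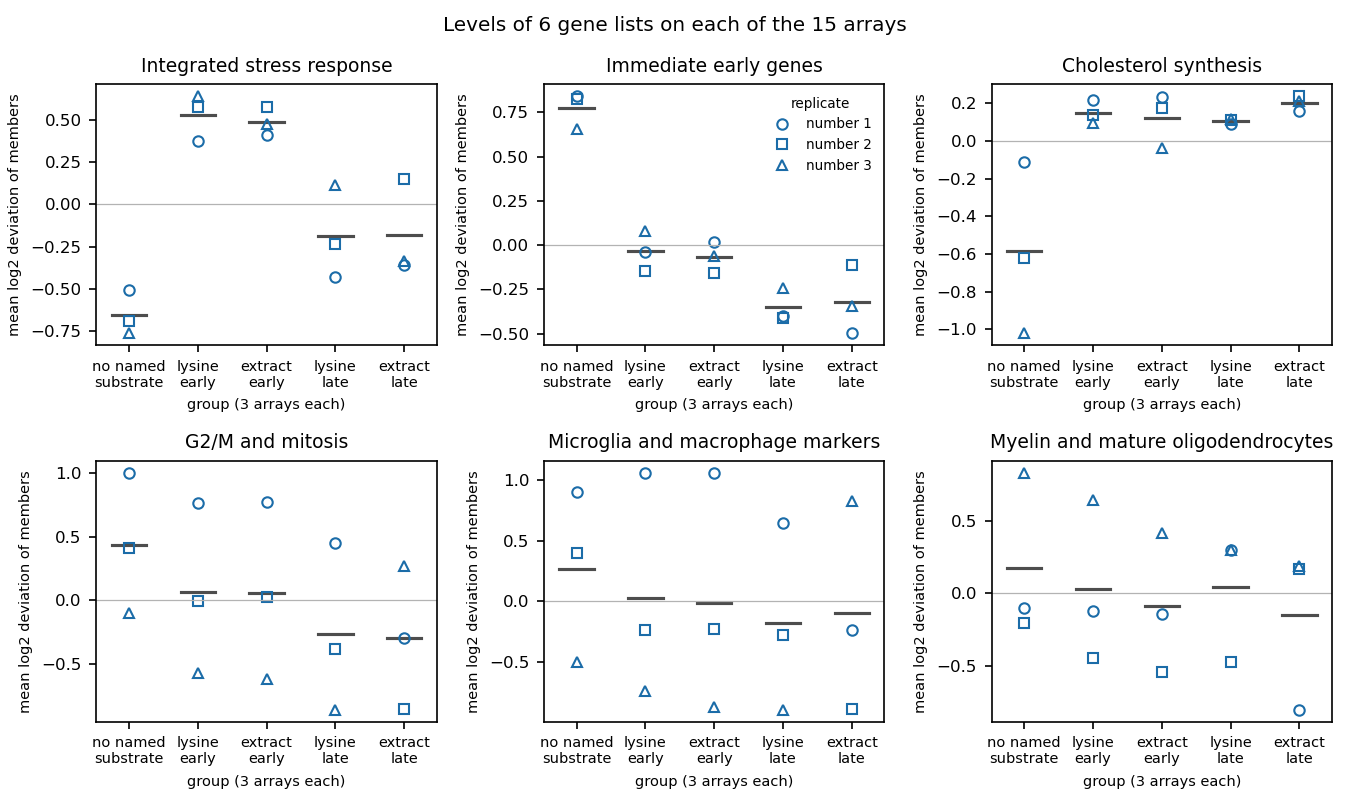
Mean log2 deviation of the members of 6 lists from each gene's mean over the 15 arrays, for each array (symbols, by replicate number) and group (bars, means of 3 arrays). Integrated stress response genes are highest in the early groups, immediate early genes are highest in the reference group, and microglia markers spread from -0.90 to 1.06 between arrays.

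At the late time on polylysine Egr1 was 15.3-fold lower than in the reference group, at 8.04 ± 0.21 against 11.98 ± 0.09 log2 units (SD, n = 3 each, adjusted p = 2.92e-06), and Fos 13.4-fold (-3.74, SE 0.262, adjusted p = 5.61e-06). Npas4, an activity-dependent transcription factor gene, fell by 2.30 (SE 0.547), Nr4a1 by 2.11, the lipid transporter gene Abca8a by 2.03, Egr2 by 2.00, Junb by 1.99 and Dusp1 by 1.86. The urokinase gene Plau (-1.94) and Ier2 (-1.94) fell as well. The genes that rose most were the inflammatory cytokine gene Il1b, 5.45-fold (2.45, SE 0.549, adjusted p = 0.0168), and Pla2g7, which encodes a secreted phospholipase of macrophages, 4.94-fold (2.30, SE 0.454, adjusted p = 0.0101). Microglia markers had a median of -0.59 in the same comparison. The aldo-keto reductase gene Akr1b8 (1.68), Asns (1.54), the small heat shock gene Cryab (1.48), Shmt2 (1.40), Acot7 (1.40), the desaturase gene Scd (1.39), the calcium-binding protein gene Pvalb (1.27) and the malic enzyme gene Me1 (1.24) also rose. Mbp differed by 0.21 (SE 0.445), Pde4d by -0.30 (SE 0.138, adjusted p = 0.205), Pdgfra by -1.07 (SE 0.427, adjusted p = 0.135) and Cspg4 by -0.67 (SE 0.301, adjusted p = 0.191). Pdgfra and Cspg4 with the block of paired numbers were called lower at adjusted p = 0.000281 and 0.0105. Over all alternatives Pdgfra ran from that value to adjusted p = 0.392 and Cspg4 to adjusted p = 0.486. In limma 1246 genes were called, 895 higher and 351 lower, with 36 and 51 at 2-fold or more, and the groups did not overlap for 3864 genes (26.7%), where chance gives 10%. A fit of these 2 groups alone called 358 genes, 283 of them higher. With arrays centred on their medians 1330 were higher and 209 lower. With the block 3254 were called, 1925 higher and 1329 lower, including all 1246, and leaving out 1 array gave 328 to 1975, with 449 and 474 without reference arrays 2 and 3 and 1975, 328 and 354 without late polylysine arrays 1, 2 and 3. The calls of Il1b (without reference arrays 2 and 3), Akr1b8 (without the same arrays and late polylysine arrays 1 and 2), Cryab (without the same reference arrays and late polylysine array 3), Scd (without late polylysine array 3) and Npas4 (without the same reference arrays and late polylysine array 2) were lost at adjusted p up to 0.0707, 0.104, 0.106, 0.0511 and 0.085.

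At the late time on the myelin extract Egr1 was 12.1-fold below the reference group (-3.60, SE 0.241, adjusted p = 8.94e-06) and Fos 9.87-fold (-3.30, SE 0.262, adjusted p = 2.77e-05). Npas4 (-2.24), Abca8a (-2.12), Nr4a1 (-2.05), Junb (-2.01), Plau (-1.95), Ccn1 (-1.93), Ier2 (-1.88) and Dusp1 (-1.88) were the next. Il1b rose 3.98-fold (1.99, SE 0.549, adjusted p = 0.0447) and Pla2g7 3.48-fold (1.80, SE 0.454, adjusted p = 0.0327), and microglia markers had a median of -0.48. Akr1b8 (1.72), Asns (1.55), the sterol pathway gene Acat2 (1.47), Acot7 (1.41), Shmt2 (1.40), Scd (1.39), Cryab (1.37) and the acetyl-CoA synthetase gene Acss2 (1.30) also rose. Mbp differed by 0.01 (SE 0.445), Pde4d by -0.21 (SE 0.138, adjusted p = 0.408) and Pdgfra by -1.21 (SE 0.427, adjusted p = 0.106, and 0.00386 to 0.397 over its alternatives), none of them called. A fit of these 2 groups alone called 0 genes higher and 12 lower. In limma on all arrays 1008 genes were called, 678 higher and 330 lower, with 35 and 47 at 2-fold or more, and the groups did not overlap for 3161 genes (21.8%), where chance gives 10%. With arrays centred on their medians 877 were higher and 231 lower. Leaving out 1 array gave 190 to 1698 calls, with 1698, 190 and 599 without late extract arrays 1, 2 and 3 and 250 and 218 without reference arrays 2 and 3. Of the 10 risen genes 1, 6 and 4 lost their call without late extract arrays 1, 2 and 3 and 1, 7 and 6 without reference arrays 1, 2 and 3, and Npas4 lost it without late extract array 3 or reference array 2 or 3. The adjusted p ran from 0.0489 to 0.166 for Il1b and from 0.0301 to 0.13 for Pla2g7.

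By list, 16 of 29 immediate early genes were lower at the late time on each substrate, 19 on polylysine and 18 on the extract adjusted over the list alone, with medians of -1.08 and -1.11 at adjusted p = 6.63e-18 and 6.52e-20. With an estimated correlation the list gave adjusted p = 0.0267 and 0.0305. CREB targets had 7 and 8 of 23 members lower, 9 on each adjusted over the list alone, at adjusted p = 2.85e-07 and 4.2e-07, and adjusted p = 0.0583 and 0.0471 with an estimated correlation. ERK feedback targets had 8 and 4 of 22 members lower, 8 and 6 adjusted over the list alone, among them the ERK inhibitor genes Spry2 (-0.78 and -0.64) and Spry1 (-0.86 and -0.76), at adjusted p = 8.94e-05 and 0.000195, and adjusted p = 0.227 and 0.237 with an estimated correlation. Unfolded protein response genes rose, 9 and 8 of 19, with 10 and 10 higher and 0 and 1 lower adjusted over the list alone, at adjusted p = 1.7e-06 and 2.48e-05. With an estimated correlation adjusted p = 0.0261 and 0.0305. The ER chaperone genes Pdia4 (0.81 and 0.77) and Hyou1 (0.89 and 0.87) were among them. Heat shock genes rose, 4 and 3 of 15, 4 on each adjusted over the list alone, with Stip1 at 0.56 and 0.59, at adjusted p = 0.0108 and 0.001, and adjusted p = 0.101 and 0.0364 with an estimated correlation. The polylysine call was lost without late polylysine array 1 (adjusted p = 0.0534). With the block of paired numbers and an estimated correlation no list was called on polylysine, where the immediate early list gave adjusted p = 0.138. The numbers of the late extract arrays did not pair, so the extract calls have no such value. A block over all 15 arrays, which rests on those numbers, ended them as well when the correlation was estimated.

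Lists of lipid and energy genes had members above the reference group at the late time. Of 22 cholesterol genes 13 were higher and 1, Lpin1 (-0.37), lower on polylysine and 15 higher on the extract, 18 higher and 1 lower on each adjusted over the list alone, with Mvk at 1.04 and 1.16 and Fdps at 1.16 and 1.28, both enzyme genes of the mevalonate pathway (adjusted p = 1.7e-09 and 4.97e-12, and adjusted p = 0.304 and 0.237 with an estimated correlation). Fatty acid synthesis had 4 and 5 of 17 genes higher, 7 and 8 adjusted over the list alone, with the citrate lyase gene Acly at 0.72 and 0.75 (adjusted p = 0.00113 and 0.00484, and adjusted p = 0.344 and 0.383 with an estimated correlation). Genes of mitochondrial respiration had 16 and 12 of 30 higher, 20 and 17 adjusted over the list alone, with Ndufb8 at 0.93 and 0.75 (adjusted p = 3.13e-14 and 9.23e-11, and adjusted p = 0.115 and 0.228 with an estimated correlation). Ribosomal protein genes had 14 and 10 of 32 higher, 25 and 13 adjusted over the list alone, with Rpl8 at 0.57 and 0.59 (adjusted p = 9.14e-12 and 3.73e-10, and adjusted p = 0.225 and 0.237 with an estimated correlation). NRF2 targets had 6 and 5 of 19 higher, 8 and 9 adjusted over the list alone, with the glutathione reductase gene Gsr at 0.59 and 0.55 (adjusted p = 4.8e-06 and 2.49e-05, and adjusted p = 0.225 and 0.237 with an estimated correlation). The hypoxia and glycolysis list had 8 of 28 higher on each, 11 higher and 2 and 3 lower adjusted over the list alone, with the glycolytic gene Pgk1 at 0.56 and 0.60 (adjusted p = 0.00373 and 0.00537, and adjusted p = 0.375 and 0.383 with an estimated correlation). Integrated stress response genes had 9 of 27 higher and 1, the lipoprotein receptor gene Vldlr (-0.53 and -0.51), lower on each, 16 and 17 higher and 2 lower adjusted over the list alone, with Phgdh, the first enzyme gene of serine synthesis, at 1.10 and 1.22 (adjusted p = 1.9e-05 and 1.82e-05, and adjusted p = 0.397 and 0.383 with an estimated correlation).

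OPC markers had 2 of 27 members lower at the late time on each substrate, over all genes and adjusted over the list alone, Cspg5 (-0.65 and -0.75) and Tmem100 (-0.91 on the extract), with medians of -0.22 and -0.24 at adjusted p = 0.0264 and 0.0149, and adjusted p = 0.413 and 0.383 with an estimated correlation. These calls were lost without late polylysine array 3 (adjusted p = 0.122, median -0.13) or late extract array 2 (adjusted p = 0.139, median -0.03), and the medians were -0.45 without late polylysine array 1 and -0.44 without late extract array 3. Mitosis genes had 0 of 32 called and medians of -0.79 on both, at adjusted p = 8.94e-05 and 1.82e-05, and adjusted p = 0.708 and 0.554 with an estimated correlation. Without reference array 1 these medians were -0.46 and -0.48, without late polylysine arrays 1 and 3 -1.20 and -0.41, and without late extract array 2 -0.47. With the block of paired numbers 24 of them were lower on polylysine at adjusted p = 9.7e-19, 8 of 28 G1/S genes were lower at adjusted p = 0.000964, 13 of 23 microglia markers were lower and 2 higher at adjusted p = 2.35e-05, and 9 of 28 NF-kB and chemokine genes were higher and 1 lower at adjusted p = 0.00106. With the block and an estimated correlation adjusted p = 0.0914, 0.306, 0.371 and 0.371. On the extract G1/S genes gave a median of -0.20 with 0 of 28 called at adjusted p = 0.0352, and adjusted p = 0.765 with an estimated correlation. The call was lost without late extract array 1 (adjusted p = 0.495, median -0.04), late extract array 2 (adjusted p = 0.174, median -0.12) or reference array 1 (adjusted p = 0.712, median -0.04), and the median was -0.42 without late extract array 3 and -0.40 without reference array 3. The myelin list gave -0.34 there with 0 of 23 called at adjusted p = 0.0157, and adjusted p = 0.708 with an estimated correlation. Its median was 0.07 (adjusted p = 0.675) without late extract array 1 and 0.01 (adjusted p = 0.518) without reference array 3, and -0.55 and -0.51 without late extract arrays 2 and 3 and -0.51 and -0.60 without reference arrays 1 and 2. The phosphodiesterase list gave -0.18 on the extract, with 1 of 20 members called, Pde3b (-0.81, SE 0.159), at adjusted p = 0.0284, and adjusted p = 0.28 with an estimated correlation. The call was lost without reference array 3 (adjusted p = 0.214, median -0.07). On polylysine the phosphodiesterase list gave adjusted p = 0.112, with Pde3b called at -0.67 (SE 0.159).

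The other lists passed in none of the comparisons without the block. In the late polylysine group against the reference group, which gave the most calls, committed oligodendrocyte genes had a median of -0.13 (adjusted p = 0.404), with the choline phosphodiesterase gene Enpp6 lower at -0.90. Wnt targets had a median of -0.09 (adjusted p = 0.161), with the cyclin gene Ccnd1 lower at -0.77, and TGF-beta and BMP targets -0.03 (adjusted p = 0.916), with the receptor gene Tgfbr1 lower at -0.65. The cAMP and protein kinase A components had a median of 0.06 (adjusted p = 0.648) with 0 of 29 called, although Adcy8 rose by 1.53 (SE 0.227) in the early polylysine group. NF-kB and chemokine genes had 2 of 28 higher, Il1b and the lipocalin gene Lcn2 (1.22), at adjusted p = 0.112, and interferon response genes 0 of 24 called at adjusted p = 0.416. The extracellular matrix list had 0 of 27 called at adjusted p = 0.916. Among lists of other cell types, microglia markers had a median of -0.59 (adjusted p = 0.112), with P2ry12, a purinergic receptor gene of resting microglia, called at -1.37. Astrocyte markers had a median of 0.08 where the test ran downward (adjusted p = 0.421), with the filament gene Gfap (-1.36) and the transporter gene Slc4a4 (-0.64) lower. Neuron markers had a median of 0.02 with a downward test (adjusted p = 0.838) and 0 of 23 called, endothelial and pericyte markers -0.05 (adjusted p = 0.332) and fibroblast markers -0.12 (adjusted p = 0.136), with 0 called in each. Schwann cell markers had a median of -0.05 (adjusted p = 0.257), with Egr2, which is also an immediate early gene, as the 1 member called. Adjusted over the list alone these counts were the same except for Wnt targets (2 lower) and astrocyte markers (3 lower). The median, mean and test did not share a sign for ERK targets and neurons against the reference group in both early groups, the interferon list in the early polylysine group, Schwann cells in the early extract group, neurons in the late extract group and endothelial markers in the late extract group. Between the times on polylysine this held for the myelin, OPC, heat shock, endothelial and Schwann cell lists, and on the extract for the committed oligodendrocyte, Wnt, G1/S, SRF and YAP, astrocyte and neuron lists, none of them called there.

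The series also holds an authors' deposited table of a comparison in tissue, 14 against 5 days after a lesion. It names no genes, and the column used here, a false discovery rate, gives no direction. Its columns of single arrays were not used. In the authors' deposited comparison 2204 of 22226 probes (9.916%) had a false discovery rate under 0.05, the smallest was 0.0001933 and the median 0.4982. Its probes could not be paired with the genes measured here, so they were not tested as a set.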

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

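The block over 4 groups, the covariate and the combinations with an estimated correlation were chosen only after the result was seen, and so were the tests of other splits of the arrays. Without a named cause in what follows, the cause was not tested.

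The counts of 0 between the substrates and in the test of substrate by time stayed at 0 in limma under every alternative run. Array weights gave 847 genes for polylysine late against early, 863 for the extract late against early, 2581 and 2194 for the early groups on polylysine and extract against the group with no named substrate, and 3154 for the late polylysine group. The covariate for the spread within groups gave 365 and 782 for late against early, 2240 and 1722 for the early groups and 2761 and 2358 for the late groups, and removes by construction spread that the other fits keep. Fits of the compared groups alone, which have fewer arrays to estimate the spread, gave 13 and 20 for late against early and 358 and 12 for the late groups. Of these, 283 of the 358 were higher, and 0 of the 13, 20 and 12. An added log2 difference of at least 1, a narrower criterion by construction, gave 28 and 40 for late against early, 121 and 108 for the early groups and 87 and 82 for the late groups. All probe sets gave 2136 for the late polylysine group, counted over more features.

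Leaving out 1 array gave 18 to 67 genes for polylysine late against early, 44 to 825 for the extract late against early, 261 to 949 and 219 to 681 for the early polylysine and extract groups, and 328 to 1975 and 190 to 1698 for the late ones. The highest counts came without array 1 of the late group or, for the early groups, array 1 of the group with no named substrate.

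Replicate numbers paired the arrays of the group with no named substrate, both early groups and the late polylysine group: the deviations of equal numbers from their group means correlated at 0.15 or more. Those of the late extract group did not pair (-0.649 to 0.305 for equal numbers). As a hint from the data, late extract array 3 correlated best with arrays 1 of each of the other groups (0.451 to 0.703) and array 2 with their arrays 3 (0.235 to 0.749). Array 1 correlated best with arrays 2 of 3 groups (0.117 to 0.385) and with array 1 of the late polylysine group (0.12). Another order of these numbers stays open, so the block over 15 arrays rests on numbers that may not pair, and the counts of 0 at the late time and in the test of substrate by time have no paired value. With the covariate, which uses no numbers, both were 0 in limma, with 377 and 189 genes at an unadjusted p under 0.05. A block over the 4 paired groups gave 514 genes for polylysine late against early, 2643 and 2022 for the early groups and 3254 for the late polylysine group, including every gene called without the block, and 0 between the substrates at the early time. The block over 15 arrays leaves each log2 difference unchanged by construction, so only the calls could change. With it all 120 results for genes named by size kept their call, and 74 of 75 list calls did.

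The 192 results on named genes gave 3121 values. Of the 1913 for genes named by size, 1709 kept direction and call, 204 lost the call and 0 reversed. The other 1208 were for the genes always named, which were not called in the main fit. Of these, 1197 stayed uncalled and 11 gained the call, and their direction was not compared. Of 75 list calls, 6 held with an estimated correlation and 0 with that and a block over 15 arrays, which ended the late calls of the immediate early and unfolded protein lists on both substrates (adjusted p = 0.0661 and 0.0643 on polylysine, 0.0628 for each on the extract) and of the CREB and heat shock lists on the extract (adjusted p = 0.0628 for each). Of 1073 values for list calls, 825 kept direction and call, 242 lost the call and 6 reversed. In fits without 1 array that kept the call, the median became over 1.5 times smaller in 21 and over 1.5 times larger in 31, and moved less in 359. Over fits without 1 array the medians ran from -0.216 to 0.0109 for the SRF and YAP targets between the substrates at the early time, -0.742 to 0.0367 and -0.741 to 0.029 for mitosis genes late against early on polylysine and extract, and -0.602 to 0.0702 for myelin genes of the late extract group. The reversals were the SRF and YAP targets between the substrates at the early time without early extract array 3 (0.0109), mitosis genes late against early on polylysine without early array 1 (0.0367) or late array 3 (0.00719) and on the extract without early array 1 (0.029), and myelin genes of the late extract group without its array 1 (0.0702) or array 3 of the group with no named substrate (0.0127).

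The sets of genes that moved on polylysine gave these medians between the substrates. Genes risen early, tested at the late time, had -0.0393 without dim genes and -0.039 with an estimated correlation, neither of them called, and -0.127 to 0.0186 over fits without 1 array, with the sign reversed without late extract array 1 (0.0186) or 3 (0.00643) and late polylysine array 3 (0.0183). Genes fallen early had -0.0359 to 0.0502, reversed without late extract array 2 (0.0502) or late polylysine array 1 (0.0295). Genes risen late, tested at the early time, had -0.101 with an estimated correlation and -0.102 with the block over 4 groups as well, neither of them called, and -0.145 to -0.04 without 1 array. Genes fallen late had 0.0598 with an estimated correlation, with and without that block and not called, and 0.00133 to 0.099 without 1 array. The correlation of early and late substrate differences, 0.237 in all, was 0.0731 to 0.409 without 1 array except late extract array 1, where it was -0.122, and its jackknife SE was 0.412.

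The 2 copies of the value table were identical, so they gave no separate values. Leaving out the group with no named substrate applies only to comparisons that do not use it. On simulated data of independent genes and unpaired arrays, 82.1 to 86.6% of genes changed 2-fold were called in the 8 comparisons of 2 groups. In the test of substrate by time it was 59.1%. Many genes were changed at once there, so the share called may be smaller where few genes change. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave 0 genes between the substrates at the early time and the highest other split 0, so 10 of 10 splits gave as many. At the late time the real split gave 0 and the highest other 1627, again 10 of 10. That split set late extract arrays 1 and 3 and late polylysine array 1 against the others and points to a structure of the samples. In the test of substrate by time the real labels gave 0 and the highest other labelling 1023, and all 100 of 100 labellings gave as many. With a real count of 0 every split or labelling gives at least as many, so these shares were fixed in advance and decide nothing. For the other comparisons 1 of 10 splits, the real one, gave as many: 95 and 195 genes for late against early, 1015 and 702 for the early and 1246 and 1008 for the late groups, with 0 as the highest other.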

Other observations

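All tests in this part were chosen only after the result was seen.

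The arrays of a group differed most in genes of microglia, the brain's resident macrophages: the mean of the 23 markers had a within-group SD of 0.858 log2 units, from -0.896 on late polylysine array 3 to 1.06 on early extract array 1, and the main component of the spread within groups held 48.9% of it. This component followed the replicate number in 4 groups, at 0.25 to 0.427 on their arrays 1 and -0.294 to -0.202 on their arrays 3, and was highest on array 3 (0.348) and lowest on array 2 (-0.357) of the late extract group. A lower share of the main cell type on some arrays would raise the markers of other cells alike, but neuron markers correlated with microglia markers at -0.454 (matched lists -0.27 to 0.204) and astrocyte and fibroblast markers at 0.57 and 0.637, while OPC markers, those of the main cell type, correlated at 0.526 (matched -0.27 to 0.202) and myelin markers at -0.308 (matched -0.28 to 0.226). Quantile normalization again left 49.1% on the main component, which argues against differences in the overall distribution of values between arrays. RMA already includes such a step, so little was left to remove, and other intensity differences were not tested. The median correlation between the microglia markers was 0.95 (matched lists -0.0729 to 0.107). A varying share of microglia would give this. Choosing the list whose mean spread most also favours markers that deviate together, so a varying share stays open. Beyond these shares of cells no biological explanation was tested, since the labels give no group for the spread within groups, and between groups the microglia markers lay lower than in the group with no named substrate with the block over 4 groups, at adjusted p = 0.00349, 0.00102 and 2.35e-05 in the early polylysine, early extract and late polylysine groups, and adjusted p = 0.635, 0.528 and 0.371 with an estimated correlation as well.

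The 895 genes that rose on polylysine by the late time lay lower on the extract at the early time, with a median of -0.101 log2 units. A shift with brightness may account for part of it, since lists drawn at random from all genes of the same level had a median of -0.0477 (5th to 95th percentile -0.055 to -0.0399). The genes of the set move together (estimated correlation 0.362), which those of random lists need not do. That range may therefore be too narrow to exclude such a shift as the whole cause. Quantile normalization again left -0.082, so differences in the overall distribution of values that it removes were not the whole cause. A difference in 1 of the 3 replicate numbers may account for most of it: the medians within equal numbers were 0.0191, -0.0363 and -0.293. An effect of the substrate stays open, and so does an effect of choosing the set on late polylysine arrays, which pair with the early ones.

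Il1b and Pla2g7 rose from the group with no named substrate to the late time, Il1b by 2.45 log2 units on polylysine and 1.99 on the extract. A larger share of microglia would raise the microglia markers as a whole, but their medians were -0.586 (quartiles -0.862 and -0.182) and -0.479 (-0.684 and -0.0894). Activation of microglia or other cells already present could raise both genes and stays open: the NF-kB and chemokine list without Il1b had a median of 0.157 on polylysine and was not called in camera with an estimated correlation, with 1 member called higher. With the block over 4 groups the list with Il1b had 9 members higher and 1 lower on polylysine at adjusted p = 0.00106, and adjusted p = 0.371 when the correlation was also estimated. The hours in culture, which the groups differ in, were not separated from these.

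A hypothesis tested on these data was that the rise of cytosolic aminoacyl-tRNA synthetase genes in the early groups may be shared with the mitochondrial enzymes. Of 19 cytosolic enzymes, which load amino acids onto tRNAs, 18 were called higher on polylysine and 16 on the extract, with medians of 0.977 and 0.945 log2 units. The 11 mitochondrial enzymes had medians of 0.106 and 0.0519. The difference of the medians was 0.871 on polylysine (permutation p = 0.00068, adjusted 0.00136) and 0.893 on the extract (permutation p = 0.00227, adjusted 0.00227, two-sided over genes), which argues against a shared rise. Genes are not independent replicates, and with an estimated correlation the cytosolic family gave adjusted p = 0.0564 on each substrate over 225 tests of 25 families. Genes with symbols of Eif and a number, a family named for translation initiation factors, had 14 and 9 of 44 called higher. The family was chosen by symbol alone, and its members were not checked for function. It kept its shift in camera with an estimated correlation at adjusted p = 0.0176 on both.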
